A study of Citrus sinensis with 5 samples.

How the data were processed

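RNA sequencing of sweet orange (Citrus sinensis) leaves was analysed in 5 libraries, 2 from plants treated for 9 months at pH 2.5 and 3 from control plants at pH 6. Per the labels' protocols, each library pooled leaves of 4 seedlings, used 3 µg of RNA and was made with a NEBNext Ultra RNA kit for Illumina sequencing. Replicate numbers were given within each treatment in the order of the samples and pair nothing across treatments. The labels give no batch. The metabolite measurements that the series title names are not analysed here.

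The submitters' processing notes name TopHat2, Cufflinks and DESeq, without versions or roles. The genome build, the annotation and the use of strand in counting are not given in the sources used here. The authors' files list the same 28766 genes for every library, with a locus, a strand and a model length. Per the file headers, the authors deposited a count per gene, which holds whole numbers and was taken as the raw count. Per the file headers they also deposited an FPKM value, the count scaled by gene length and library size. A column of normalized values, a signal that equals the count multiplied by nearly 1 factor per library, was also deposited; those factors were 0.877 and 0.804 in low pH replicates 1 and 2 and 1.10, 1.11 and 1.12 in control replicates 1, 2 and 3.

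Of the 28766 identifiers, 0 matched the locus tags, synonyms or accessions of the RefSeq gene table for this species that was at hand. The 39 lists of genes fixed by product name before the data were examined were therefore not used, and no identifier was given a name. Genes were instead grouped by abundance, model length, exon structure, the label newGene, chromosome and overlap, in 23 groups chosen after the files had been seen. The rule for the genes described singly was fixed before the data were examined. It took, for want of names, the 2 largest rises and 2 largest falls in log2 fold change among genes past the threshold, with a mean of at least 5 CPM in the higher treatment and library values that do not overlap between treatments.

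The comparison used edgeR 4.0.16 in R 4.3.3 on the deposited counts, with trimmed-mean (TMM) factors (1.07 and 1.10 in low pH replicates 1 and 2, and 0.926, 0.946 and 0.964 in control replicates 1, 2 and 3), genes kept by filterByExpr, the quasi-likelihood test, 2-sided, and a Benjamini-Hochberg adjusted p under 0.05. This left 16946 genes. The design was fixed before the data were examined. Fold changes are low pH minus control on the log2 scale. Standard errors were taken from the fold change and the test statistic, and can understate even counting error for genes with few counts in one treatment. CPM values use the TMM-scaled library sizes, and shares of counts use raw totals. Abundance ranks of gene groups follow mean CPM over all 5 libraries, and those of shares follow mean share. The common biological coefficient of variation was 23.7%.

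Gene groups were tested with camera and fry (limma 3.58.1) on log2 CPM with a prior count of 2, with a preset correlation of 0.01 and with an estimated one. Fry asks whether a group's genes move on balance in one direction, without comparing them with other genes. Fisher's exact test compared the directions of called genes inside and outside a group and treats genes as independent, which they are not. All were adjusted over the 23 groups. Adjacent tested genes on chromosomes 1 to 9 whose loci do not overlap were compared with 10000 shuffles of directions within chromosomes, leaving out 1156 overlapping pairs, and a distance of 5 kb separated near from far pairs. Rank correlations of fold changes between neighbours used 1000 shuffles.

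The alternatives fixed beforehand were DESeq2 1.42.0, edgeR's likelihood ratio test, robust estimation, limma-voom, limma on log2 of the authors' FPKM plus 1 or plus 0.1 (genes with a mean of at least 1), median ratio and upper quartile factors, library totals alone, no count filter, a minimum of 1 CPM in 2 libraries, a change of at least 2-fold, an adjusted p under 0.01, and leaving out each library in turn. With 1 low pH library left, that library is assumed to vary like the controls. The factors of the authors' normalized column, removal of each library's trend on gene length, leaving out overlapping loci and leaving out the 30 most abundant genes were added after seeing the data, as were other rankings of abundance, with the treatments weighted equally, in the libraries of one treatment alone, or within each library.

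The comparison was tested on simulated data, 10 sets of counts for the 16946 genes with 200 genes changed in each. It recovered 25.7% of genes changed 2-fold and 74.6% of genes changed 4-fold, with median fitted log2 fold changes of 1.00 and 2.00. False calls made up 10.5% of calls, above the nominal share, and at most 2 genes were called when none was changed. Depth was 17224516 to 21505928 counts per library. Intervals for ratios of counts are exact 95% binomial intervals and cover counting error only, as reads without molecular identifiers are not independent molecules.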

Results

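Leaf messenger RNA was measured by RNA sequencing in seedlings of sweet orange, Citrus sinensis, that had been treated for 9 months at pH 2.5 (low pH) or pH 6 (control). The question, as the labels and the series title put it, was how leaf gene expression differs after long exposure of the plants to acid. There were 2 low pH libraries and 3 control libraries. Each library came from the leaves of 4 seedlings mixed in equal amounts, and the labels call the libraries biological replicates. Total gene counts were 20178803 and 21505928 in low pH replicates 1 and 2, and 18710578, 17734326 and 17224516 in control replicates 1, 2 and 3. Between 19088 and 19647 of the 28766 listed genes had at least 1 count in a library, and 7770 genes were at 0 in every library. At these depths a count of 0 allows up to 0.127 to 0.181 CPM (counts relative to the library size after trimmed-mean scaling), taking 3 counts as the upper limit, which covers counting error only.

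The first principal component of log2 CPM held 53.6% of the variance and separated the treatments, with low pH libraries at -49.4 and -65.3 and control libraries at 30.5, 43.1 and 41.1. Spearman's rho across genes, which are not independent replicates, was 0.975 to 0.984 between libraries of one treatment and 0.939 to 0.956 between treatments. The counts of no libraries of one treatment agreed within counting noise, with a chi-square per degree of freedom of 34.9 to 61.3, a limit that repeated preparations of one RNA would also be likely to pass.

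After 9 months at pH 2.5 the leaves showed a broad change in both directions. Of 16946 genes tested, 1209 were higher and 1406 lower at low pH, or 15.4% of those tested, by edgeR's quasi-likelihood test with a Benjamini-Hochberg adjusted p under 0.05. Most changes past the threshold were moderate. Smaller changes are harder to call, so the medians that follow describe the called genes only. The median log2 fold change was 0.90 among the genes that rose and -0.91 among those that fell, while 113 genes rose and 122 fell by 4-fold or more. All 2615 of these genes had low pH and control libraries that did not overlap, as did 9024 of all genes tested, or 53.3%, where chance gives 20%. No gene was at 0 in every library of one treatment with at least 10 counts in each library of the other, in either direction. The number of genes past the threshold depended on single libraries. It was 364 without low pH replicate 2, 1033 without control replicate 1, 322 without control replicate 2 and 74 without control replicate 3, against 2029 without low pH replicate 1. At an unadjusted p under 0.05 the number fell less. By the same test it was 5957 with all 5 libraries and 5323, 4778 and 4633 without control replicates 1, 2 and 3. The balance of directions depended on the scaling. With trimmed-mean (TMM) factors 46.2% of the genes past the threshold were higher at low pH, and with library totals alone 75.6% were higher, as that scaling moved the median log2 fold change of all genes from 0.02 to 0.23.

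**Figure D1:**
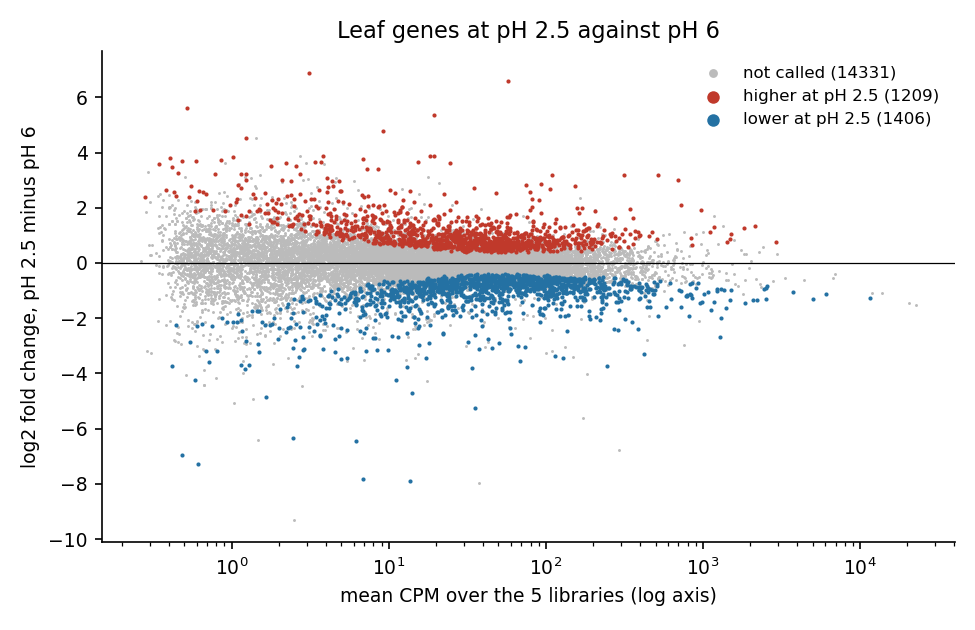
Each point is a gene, with its mean CPM over the 5 libraries on a log axis and its log2 fold change (pH 2.5 minus pH 6) on the vertical axis. Red points mark the 1209 genes that were higher at pH 2.5, blue points the 1406 that were lower, and grey points the other genes tested; the blue points reach further to the right, among the most abundant genes.

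Among genes past the threshold with a mean of at least 5 CPM in the higher treatment, those with the largest changes had few reads in the other. The files pair no identifier with a gene name, so these genes are given by identifier and position, on the authors' genome build, which is not given in the sources used here. Cs3g14050, on the minus strand of chromosome 3 from 18456149 to 18457104, rose from 0.0592 ± 0.00133 CPM (SD, n = 3) in control leaves to 7.71 ± 0.338 CPM (SD, n = 2) at low pH. Its log2 fold change was 6.88 (SE 0.36, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00574), and its counts were 172 and 177 against 1 in each control library. The ratio of its scaled totals was 130, with an exact 95% interval of 44.1 to 634. The gene orange1.1t01447, on the minus strand of an unplaced sequence from 24440418 to 24442567, rose from 1.46 ± 0.649 CPM (SD, n = 3) to 141 ± 82.7 CPM (SD, n = 2), a log2 fold change of 6.59 (SE 0.50, edgeR adjusted p = 0.00872). Its low pH libraries differed from each other, with counts of 4317 and 1953 against 20, 37 and 17 in the controls, and its locus overlaps 1 other gene, on the plus strand from 24441547 to 24442566. That gene had counts of 1547 and 521 at low pH against 10, 35 and 12 in the controls. The reads of these overlapping genes cannot be told apart unless the counting used strand, which is not given in the sources used here, so the fold change printed for orange1.1t01447 may hold reads of both.

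Among the genes of that kind that fell, Cs8g19470 and orange_newGene_2145 changed most. Cs8g19470, on the minus strand of chromosome 8 from 21650630 to 21651135, fell from 22.7 ± 5.12 CPM (SD, n = 3) in control leaves to 0.0884 ± 0.00566 CPM (SD, n = 2) at low pH. Its log2 fold change was -7.90 (SE 0.38, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00574), with counts of 366, 310 and 471 in the controls against 2 in each low pH library. The ratio of its scaled totals, control over low pH, was 257, with an exact 95% interval of 99.9 to 943. The gene orange_newGene_2145 lies on the plus strand of an unplaced sequence from 6396436 to 6400630. It fell from 11.4 ± 5.67 CPM (SD, n = 3) to 0.0442 ± 0.00283 CPM (SD, n = 2), with a log2 fold change of -7.82 (SE 0.84, edgeR adjusted p = 0.0124). Its counts were 273, 226 and 83 in the controls and 1 in each low pH library, a ratio of scaled totals of 260 with an exact 95% interval of 71.7 to 2155. Without low pH replicate 2 its adjusted p was 0.0540, the highest over the alternatives. The intervals cover counting error only, and those of Cs3g14050, Cs8g19470 and orange_newGene_2145 are wider than their SEs imply. For each of these genes, every library of the lower treatment had the same count. The SD of that treatment therefore reflects library size alone. Of the 4 genes described singly, Cs3g14050 and Cs8g19470 have a model as long as their locus, without introns. The loci of orange1.1t01447 and orange_newGene_2145, at 2150 and 4195 bases, are longer than their models of 1418 and 2861 bases.

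**Figure D2:**
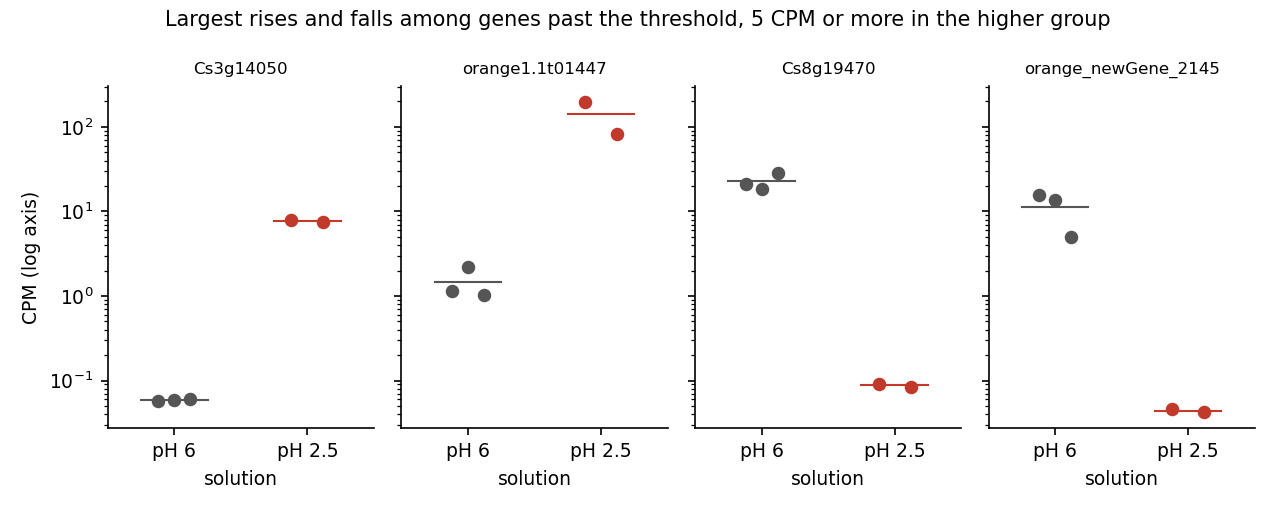
CPM of the 4 genes with the largest rises and falls among genes past the threshold with at least 5 CPM in the higher treatment, on a shared log axis, in each pH 6 library (grey, n = 3) and each pH 2.5 library (red, n = 2); bars mark the group means. In every panel all points of one treatment lie apart from all points of the other, as in Cs8g19470, with means of 22.7 and 0.0884 CPM.

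The most abundant transcripts of the leaf took a smaller share of all counts at low pH. The 5 genes with the highest mean share took 4.58% ± 1.26 (SD, n = 2) of all counts at low pH and 10.02% ± 1.10 (SD, n = 3) in controls. For the top 30 genes the shares were 11.5% ± 1.36 (SD, n = 2) and 18.4% ± 0.744 (SD, n = 3), and for the top 100 they were 20.0% ± 1.44 (SD, n = 2) and 27.0% ± 1.10 (SD, n = 3). Every low pH library lay below every control library in each of these shares, and a 2-sided exact permutation test gave p = 0.1 each time, the smallest value that 10 splits allow. Genes were ranked over all 5 libraries, of which 3 are controls. The same 5 genes led when the treatments were weighted equally and when low pH or control libraries were ranked alone, and each library's own top 100 genes took 20.9% ± 0.926 (SD, n = 2) at low pH and 27.5% ± 1.04 (SD, n = 3) in controls. Most of this difference lay in the top 5, as ranks 6 to 100 of each library took 16.3% ± 0.301 (SD, n = 2) and 17.5% ± 0.311 (SD, n = 3). Of the 100 most abundant genes 30 were lower, 9 higher and 61 not past the threshold, with a median log2 fold change of -0.53. The direction of those calls differed from that of other genes (Fisher's exact test, 2-sided, adjusted p = 0.00958 over 23 groups of genes). Adjusted over the list alone, 41 were lower and 13 higher, but the list was chosen after the files had been seen and ranked on these same counts. The camera test gave an adjusted p of 7.73e-05 with a preset correlation between genes of 0.01, and the call was lost with an estimated correlation (adjusted p = 0.425); the rotation test fry gave an adjusted p of 0.0729. Of the 30 most abundant genes 10 were lower and 2 higher, with a median of -0.80, where Fisher's exact test gave an adjusted p of 0.103 and camera 2.28e-04, again lost with an estimated correlation (adjusted p = 0.425). Each of the top 5 genes had a lower share in every low pH library than in every control library, with log2 fold changes of -1.53 to -1.08, but only 1 of them passed the threshold, at -1.27 (SE 0.27, edgeR quasi-likelihood, adjusted p = 0.0320). The number of lower genes in the top 100 was 24 without low pH replicate 1, 3 without low pH replicate 2, and 11, 4 and 1 without control replicates 1, 2 and 3. In that group DESeq2 gave 51 lower and 16 higher, and library totals alone 26 lower and 15 higher. The direction beyond the top 5 depended on the ranking. The top 30 genes of the low pH libraries alone had a median log2 fold change of 0.31, with 4 lower and 7 higher, against -0.72, with 9 lower and 3 higher, when the treatments were weighted equally. For the top 100 genes the low pH ranking gave a median of -0.13, with 17 lower and 14 higher. Weighting the treatments equally gave -0.46, with 27 lower and 13 higher.

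**Figure D3:**
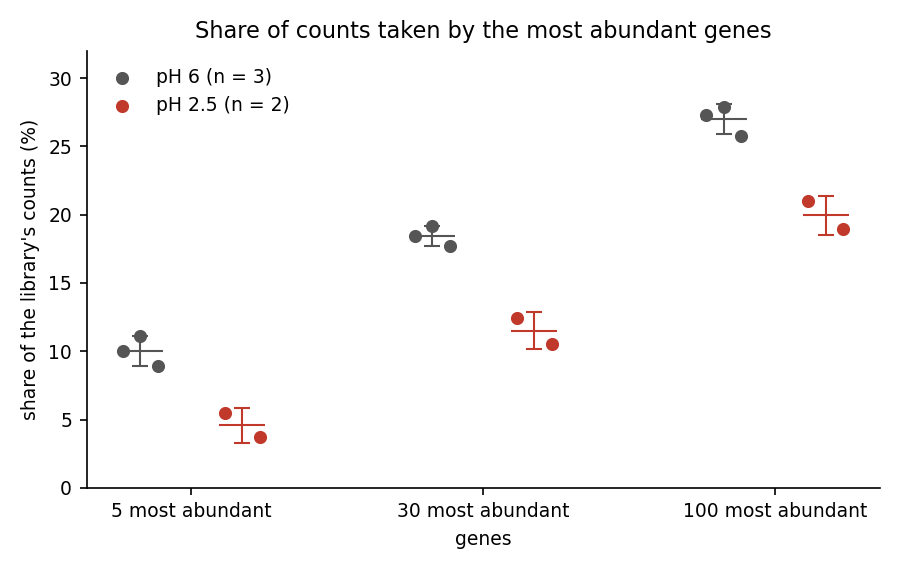
Share of each library's counts, in percent, taken by the 5, 30 and 100 most abundant genes at pH 6 (grey, n = 3) and pH 2.5 (red, n = 2). Points are libraries and bars are the mean and SD; for the top 5 genes the means are 10.02% and 4.58%, and no low pH library reaches a control library.

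With TMM scaling lower genes outnumbered higher ones among those past the threshold down to rank 5000, and with library totals alone the balance flipped in the 900 genes down to rank 1000 (116 lower and 160 higher) and in the 4000 after them (304 lower and 837 higher). Among the next 900 genes, down to rank 1000, 163 were lower and 70 higher (Fisher's exact test, 2-sided, adjusted p = 1.50e-06; camera adjusted p = 0.0522, and 0.594 with an estimated correlation). Among the 4000 genes after those, 523 were lower and 378 higher, with a median log2 fold change of -0.05 (Fisher's exact test, adjusted p = 0.00489; camera adjusted p = 0.217, and 0.425 with an estimated correlation). Among the 11946 genes below rank 5000, 690 were lower and 752 higher, with a median log2 fold change of 0.07 (Fisher's exact test, adjusted p = 2.19e-10; camera adjusted p = 0.0547, and 0.425 with an estimated correlation). Library totals alone gave 455 lower and 1787 higher there. Without control replicates 1, 2 and 3, in that order, the 900 genes had 66 lower and 32 higher, 24 and 11, and 7 and 0. The 4000 genes had 218 lower and 151 higher, 81 and 43, and 21 and 9. Those below rank 5000 had 314 lower and 238 higher, 86 and 73, and 20 and 16, where the balance flipped. It also flipped there without low pH replicate 2, but not without low pH replicate 1. Other rankings were not tried on these ranges. These and the following groups were defined after the files had been seen.

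Among genes past the threshold, the shortest were mostly higher and the longest mostly lower, while the numbers of higher genes in these groups were not tested against each other. In the shortest 10% of tested genes, 1695 genes with a median model length of 788 bases, 138 were higher and 61 lower at low pH (Fisher's exact test, 2-sided, adjusted p = 1.98e-10; camera adjusted p = 0.0547, and 0.425 with an estimated correlation). In the longest 10%, with a median length of 4696 bases, 84 were higher and 165 lower (Fisher's exact test, adjusted p = 1.22e-04; camera adjusted p = 0.332, and 0.878 with an estimated correlation), a direction that flipped to 238 higher and 98 lower with library totals alone. That scaling raised all genes alike and gave 241 higher and 48 lower in the shortest 10%. With each library's trend on gene length removed, 91 were higher and 93 lower in the shortest 10%, and 119 higher and 139 lower in the longest. Without low pH replicate 1 the shortest 10% had 88 higher and 68 lower genes, without low pH replicate 2 it had 20 and 10, and without control replicates 1, 2 and 3 it had 51 and 34, 16 and 12, and 7 and 5. In the longest 10% the same libraries, left out in that order, gave 87 higher and 93 lower, 7 and 25, 32 and 67, 8 and 23, and 1 and 7.

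Loci that carry the label newGene, which are named apart from the other gene models, passed the threshold less often than other genes, at 9.14% against 15.6% (Fisher's exact test, 2-sided, adjusted p = 4.07e-05). Over all genes this share fell with abundance, from 39.0% of the 100 most abundant to 12.1% below rank 5000. Quartiles of log2 fold change were -0.30 and 0.72 in newGene loci and -0.37 and 0.39 in other genes. With at least a 2-fold change required, 29 newGene loci were higher and 10 lower, against 1096 called of all 16946 genes tested. Abundance was not matched, so the lower share does not show a weaker response of newGene loci. Of 558 such genes tested, 507 did not pass, 39 were higher and 12 lower, with a median log2 fold change of 0.21 (Fisher's exact test on direction, 2-sided, adjusted p = 5.70e-05; camera adjusted p = 0.0547, and 0.594 with an estimated correlation). The counts were 23 higher and 9 lower without low pH replicate 1, 3 and 3 without low pH replicate 2, and 20 and 9, 3 and 5, and 4 and 1 without control replicates 1, 2 and 3.

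Changed genes lay on every chromosome. Across chromosomes 1 to 9 between 14.1% and 17.2% of the tested genes passed the threshold, and no chromosome stood out in how many passed or in their direction (smallest adjusted p of 0.158 and 0.103 by Fisher's exact test, 2-sided). Neighbouring genes changed in the same direction more often than shuffled ones. Of 13186 pairs of adjacent tested genes with loci that do not overlap, 193 changed in the same direction, against a mean of 160 when directions were shuffled within chromosomes (permutation test, one-sided, p = 0.0045, adjusted p = 0.0315 over 21 relations), and 144 pairs changed in opposite directions, against 158. Among divergent pairs, which lie head to head on opposite strands, 64 changed in the same direction against a shuffled mean of 41.1 (permutation p = 4e-04, adjusted p = 0.0084). Convergent pairs, which lie tail to tail, numbered 37 against 34.3 (permutation p = 0.343), and pairs on the same strand 92 against 84.7 (p = 0.219). The difference between divergent and convergent pairs itself had a one-sided permutation p of 0.0101, and that between opposite and same strands, the other contrast computed, 0.0773, both unadjusted. Rank correlations of the fold changes of all neighbours, past the threshold or not, were not limited to divergent pairs. Across genes, which are not independent replicates, Spearman's rho was 0.0409 over all pairs, 0.0422 on the same strand and 0.0523 in divergent pairs (one-sided permutation p = 0.000999 each, the smallest that 1000 shuffles can give, adjusted p = 0.00175 over 7 relations), and 0.0226 in convergent pairs (permutation p = 0.124, adjusted p = 0.124). All these shuffles kept the 5 libraries fixed, so their p-values measure spread over genes and not over replicates. Neighbours were not compared between libraries of one treatment, so the excess cannot be assigned to acid. The number of same-direction pairs was 40, 8 and 1 without control replicates 1, 2 and 3, as fewer genes passed the threshold. No shuffled mean was computed for those counts, so they do not show whether the excess held.

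Cs8g19470 lay in the region with the strongest decline among 16 runs of at least 3 adjacent changed genes of one direction. Its region, on chromosome 8 from 21641473 to 21654832, held 4 genes that fell, with log2 fold changes of -7.90 to -1.11. On chromosome 9 from 16559500 to 16605439, 4 adjacent genes rose by 0.70 to 1.03 on the log2 scale. On chromosome 5 from 12889581 to 12901784, 3 adjacent genes fell, with a median log2 fold change of -1.90, and on chromosome 9 from 8476450 to 8540169, 3 rose, with a median of 1.28. Adjacent means next to each other among tested genes, and both chromosome 9 regions also held 1 listed gene that was not tested. The number of runs, 16 against a shuffled mean of 10.7, did not pass the threshold (permutation test, one-sided, p = 0.0738).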

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

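The authors' factors, the removal of the length trend and the exclusion of overlapping loci and of the 30 most abundant genes, and other rankings of abundance, were tried only after the data had been seen. Of 66 counts of changed genes (in all, higher and lower) under 18 planned and 4 added alternatives, 43 stayed within 1.5 times the reported ones. DESeq2 gave 4068 genes, 1816 higher and 2252 lower. Library totals alone gave 2799 higher and 901 lower. Requiring a 2-fold change left 1096 genes, 506 higher and 590 lower, and an adjusted p under 0.01 left 20, 9 higher and 11 lower. Leaving out single libraries gave 74 to 2029 genes, 25 to 945 higher and 49 to 1084 lower; fewer libraries are part of the construction, and why control replicate 3 mattered most was not tested. The count was 1033 without control replicate 1, 322 without control replicate 2, 74 without control replicate 3 and 364 without low pH replicate 2. For the other differences the cause was not tested. All 87 values of the 4 genes described singly kept their direction, which leaving out a library could not turn since their treatments do not overlap, and 85 kept their side of the threshold; the log2 fold changes ranged from 3.75 to 7.07 for Cs3g14050, 5.81 to 7.09 for orange1.1t01447, -8.09 to -5.84 for Cs8g19470 and -8.18 to -2.51 for orange_newGene_2145, whose exceptions were an adjusted p of 0.0540 without low pH replicate 2 and of 0.0124 against the 0.01 threshold. With overlapping loci left out orange1.1t01447 has no value. Of 330 counts in gene groups and neighbour pairs, 122 moved by over 1.5 times. The difference in the share of the top 5 genes, low pH minus control, was -6.33 to -4.54 percentage points with single libraries left out, and -5.44 to -5.41 under 4 other rankings of abundance. The 25.7% of 2-fold changes recovered in simulations holds for 200 changed genes of 16946; with more changed genes the adjusted threshold is less strict, so that share was not measured for these data.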

Other observations

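The tests on abundance under library totals, on the ranking of abundant genes, on the distance of divergent neighbours and on the rank correlation between neighbours were chosen only after the results they bear on had been seen, as was the removal of the length trend.

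Genes whose model is as long as their locus, and so without introns, passed the threshold less often than the rest. Of 1841 tested, 97 were higher and 142 lower at low pH, or 13.0%, against 1112 higher and 1264 lower of 15105 genes with several exons, or 15.7% (Fisher's exact test, 2-sided, adjusted p = 0.00429 over 23 groups, with genes taken as independent). Their direction showed no difference past the threshold from that of other genes (Fisher's exact test, adjusted p = 0.128). Their fold changes spread wider, with quartiles of -0.62 and 0.48 against -0.35 and 0.39 for genes with several exons. Over all genes the share past the threshold fell with abundance, from 39.0% of the 100 most abundant to 12.1% below rank 5000. Abundance was not matched, so the lower share does not show a weaker response of genes without introns. On unplaced sequences 166 genes were higher and 221 lower of 2595 tested, and among genes whose locus overlaps another 270 were higher and 287 lower of 3395, with adjusted p for direction of 0.257 and 0.360 by Fisher's exact test. These counts were made with all 5 libraries, and leaving out single libraries was not tried on them.

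The 30 most abundant genes had a median log2 fold change of -0.80 at low pH, with 10 lower, 2 higher and 18 not past the threshold; Fisher's exact test gave an adjusted p of 0.103, and the camera call was lost with an estimated correlation (adjusted p = 0.425). The choice between TMM factors and library totals moved the median of all genes only from 0.02 to 0.23, too little to account for the negative median. With library totals alone the median of the 30 genes was -0.6033. Their share of raw counts, which rests on the same totals, was lower in each low pH library than in each control library. A trend on gene length does not account for the negative median either. With that trend removed the median was -0.7767, below the lowest of 1000 random sets of 30 genes (-0.454). The choice of genes stays open: with the treatments weighted equally the median was -0.72, but the 30 genes ranked in the low pH libraries alone, a choice that favours genes high at low pH, had a median of 0.3121, so for genes beyond the top 5, which are the same whichever treatment is ranked, a response to acid cannot be told apart from the ranking. Leaf age and time of sampling were not tested.

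Short genes were higher at low pH relative to long genes, by 0.23 on the log2 scale between the medians of the shortest and the longest 10%. Low counts of short genes may account for part of it, as the difference among genes above the median abundance was smaller, at 0.1368 (bootstrap 95% interval 0.0670 to 0.229, over 340 short and 1223 long genes). That difference stayed above 0, which argues against low counts as the whole cause. The bootstrap takes genes as independent, within the same 5 libraries. A length trend that arises between libraries for technical reasons, such as RNA quality or fragment size, cannot be told apart from an effect of the treatment: libraries of one treatment differed by up to 0.1135, more than the smallest difference between a low pH and a control library, 0.0692. With the trend removed the difference was 0.03, which shows only that the correction worked.

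Neighbouring genes changed in the same direction more often than shuffled ones. The shuffles kept the 5 libraries fixed, so an excess that any 2 libraries show cannot be told apart from a response to acid. Reads shared by adjoining genes are unlikely as the whole cause of the rank correlation. At gaps of 5 kb or more Spearman's rho was 0.0544 across 6324 pairs of genes, which are not independent replicates. Its permutation p was 0.000999, the smallest 1000 shuffles can give (adjusted p = 0.00175). For the count of pairs this stays open, as 92 against a shuffled mean of 76.8 did not pass once adjusted (permutation p = 0.0417, adjusted p = 0.109). Tandem copies on 1 strand would not raise the number of pairs on opposite strands, which had a permutation p of 0.003. That count does not bear on copies that lie on opposite strands, which were not tested. A start region that divergent genes have in common would act over short distances. Divergent pairs 5 kb or more apart numbered 35 against 23.4, which did not pass once adjusted (permutation p = 0.0125, adjusted p = 0.0504). Their rank correlation passed (Spearman's rho 0.0613, permutation p = 0.002, adjusted p = 0.0028). Closer ones numbered 29 against 17.7 (permutation p = 0.0079, adjusted p = 0.0415), but their rank correlation did not pass (permutation p = 0.0699, adjusted p = 0.0816). The excess of divergent pairs held with DESeq2 (128 against 98.7), limma-voom (60 against 38.8), library totals alone (129 against 104.9) and the length trend removed (61 against 41.9); regional base composition, which neighbours have in common, was not tested and stays open.

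The comparison of 2 with 3 libraries allows 10 splits of the samples, too few for a share under 0.05. The real split gave 2615 genes, 1 split of 10 with as many, and the highest of the other splits gave 0. Every other split mixes low pH and control libraries within a group, which widens the spread there and lowers the calls. That 0 is therefore no measure of how many calls would arise without a treatment difference.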
